A study of Mus musculus with 4 samples.

How the data were processed

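Total RNA of whole liver from male mice was labelled with Cy5 and hybridized to Agilent mouse 1-colour arrays, 1 array for each of 4 groups, per the labels' protocols. The groups are called control (naturally aged mice), diabetic (aged diabetic mice), metformin (aged diabetic mice given metformin) and combination (aged diabetic mice given astragalus polysaccharide and metformin). The labels carry 60 d in their titles without saying what the time counts from. Whether RNA of several mice was pooled on an array is not given in the sources used here. All 4 arrays lay on 1 slide with 1 scan time, so neither slide nor scan separates them. Batches of RNA extraction and labelling are not given in the sources used here.

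Each array's scanner file holds spot intensities as deposited. Per the file headers they were made with Feature Extraction 11.5.1.1 under a red-channel 1-colour protocol on a grid built for mm9, while the submitters' processing notes name Agilent Feature Extraction 10.7. The intensity used here is the processed signal, which the software had already corrected for background. The authors' value table holds log2 values per the labels and the files: set against the same array's log2 processed signal it correlated at 0.999 to 1.00 across probes with slopes of 0.986 to 1.01. Its columns have the same median, 7.84, and the same 75th percentile, 11.1, which fits a quantile normalization between arrays, although the labels name only GeneSpring and no method. Its direction and scale are therefore known, and its exact normalization is not.

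The main values were log2 processed signals minus the 75th percentile of the array's non-control probes, with each probe's spots averaged. Spots marked by the software as non-uniform or as population outliers were left out. These were 3.31% of 59305 non-control spots on the control array, 4.66% on the diabetic, 5.35% on the metformin and 2.18% on the combination array. No spot was saturated. A probe counted as above background where at least 50% of its remaining spots were marked well above background. That held for 29398, 29828, 31867 and 31980 of 56605 probes on the control, diabetic, metformin and combination arrays. The 75th percentile signal was 1560, 1678, 1961 and 2167 in the same order. Against the control array its log2 differed by 0.11, 0.33 and 0.47 on the diabetic, metformin and combination arrays, and 6 spike-in probes differed by medians of -0.01, -0.14 and 0.12, so a scale set by the spike-ins would place more genes higher on the treated arrays. Outliers were mostly bright: above the 75th percentile of all spots they made up 10.4%, 14.0%, 14.5% and 6.31% of spots in the same order. With them kept, the 75th percentile of the diabetic array would lie 0.38 higher in log2 and that of the combination array 0.15 higher. Levels on the combination array are thereby set too low against the diabetic array by 0.23 in log2, and differences for that array are reported after the median difference of all measured genes is taken off. That centring was chosen after seeing the data.

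The files give accessions and no gene symbols, so 33767 probes (59.7%) were named through the RefSeq gene table of GRCm38.p6, giving 23462 symbols. The other 22838 probes carry no name here and enter no gene count. The table's assembly differs from the grid's, so no coordinates are printed. A gene's difference is the mean over its probes measured above background on both arrays. Different probes of 1 gene differed by a median SD of 0.19 to 0.22 in log2, with a long tail, so a gene on 1 probe is less certain than one on several. A gene not well above background on 1 of 2 arrays has only a bound: the bright level against the higher of the dim probe's own value and the lowest signal among probes above background on that array.

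With 1 array per group no test of a group difference is possible, and no p-value is given. Genes at least 2-fold apart were counted. The spread of repeated spots gives a technical SD of 0.09 to 0.10 in log2 for a difference between 2 arrays, which leaves out differences between mice, RNA preparations and hybridizations. For 35 gene lists fixed before the data were examined, the median log2 difference of at least 5 measured members was placed among 10000 random lists of the same size matched on expression in 20 bins. A list is said to stand apart outside the central 95%, which describes these arrays and is not a test. With 35 lists and 4 comparisons some lists pass this mark by chance. Up to 58 list members in a comparison had no value because of outlier spots, among them Fasn.

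Named genes followed a rule fixed before the data were examined. It takes the 8 highest and 8 lowest differences in each comparison among genes above background on both arrays whose brighter value is above the median of such genes on that array, whose probes share a sign and which have a plain gene symbol. It adds the 2 largest bounds each way and, in a list that stands apart, the 4 members furthest in the list's direction. A gene named in 1 comparison may be given in the others. Some genes that the rule takes are not reported here. Members of near-identical families (Mup, Cyp2, Cyp3a, Cyp4a, Serpina, Hba and Hbb, Ig and H2), and the trypsin genes, can share signal through cross-hybridization.

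The steps were tested on simulated data for diabetic against control, with 13475 genes and a noise SD of 0.1. All 100 genes planted at a log2 change of 1.5 and all 100 planted at 2 were called, with 0 unchanged genes called. A list planted 0.5 higher lay above all random lists, and 4 of 100 unchanged lists fell outside the central 95%. The simulated noise was independent between probes, and the unchanged lists were drawn at random, as the random lists are. These results therefore check the calculation and not how often 2 single livers would give such differences.

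The alternatives were genes above background on all 4 arrays, no filter on background, the 75th percentile over probes above background on all arrays, quantile normalization, centring on the array median, normexp background correction (offset 50), the brightest probe per gene, the authors' log2 values and a 1.5-fold threshold. Normexp was run on the median spot signal, since the files hold no mean signal. Keeping outlier spots and centring on the median gene were added after seeing the data. The 75th percentile over probes above background on all arrays, centring on the array median and centring on the median gene each subtract a single constant per array. They move a list and its random lists alike. A list's percentile can differ there only through new random draws and slight changes of the expression bins. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.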

Results

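Liver RNA of male mice was profiled on 4 Agilent 1-colour arrays, 1 per group: naturally aged control mice, aged mice with type 2 diabetes, aged diabetic mice given metformin, and aged diabetic mice given metformin together with astragalus polysaccharide. Metformin is a glucose-lowering biguanide, and astragalus polysaccharide is a carbohydrate fraction of Astragalus root. The arrays correlated with one another at 0.950 to 0.965 across the 24363 probes above background on all 4. There are no replicates, so every difference given here is one between single arrays, in log2 or as a fold, and the number of arrays limits its precision.

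The first comparison asks how the diabetic liver differed from the aged control liver. On the diabetic array the steroid-synthesis enzyme gene Cyp17a1 was 40.5-fold higher and the fatty acid omega-hydroxylase genes Cyp4a14 and Cyp4a10, which PPAR-alpha induces, were 28.4-fold and 17.4-fold higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 12.7-fold higher, and Mogat1, which makes diacylglycerol, was 11.5-fold higher. Slco1a1, an organic anion transporter abundant in male mouse liver, was 37.8-fold lower, and several pancreatic digestive enzyme genes were 11.8-fold to 99.1-fold lower. Of 13475 genes measured on both arrays, 1028 were at least 2-fold higher and 596 at least 2-fold lower. With outlier spots kept, the split became 893 higher and 793 lower.

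The other leading higher genes were Phlda3, a p53 target (36.1-fold), the imprinted transcript H19 (27.9-fold), Hamp, which encodes the iron hormone hepcidin (21.5-fold), the cadherin-family gene Cdhr2 (20.4-fold) and Slc22a27 (15.4-fold). Among the lowest were Amy2b (99.1-fold lower), Serpina4-ps1 (61.1-fold lower), Slco1a1, and the pancreatic genes Cel, Cpa1, Cpb1 and Cela3a, which were 24.8-fold to 31.4-fold lower. Each rested on 1 probe, except Cyp4a10 and Slco1a1 with 2, and members of the Cyp4a, Serpina and other near-identical families can share signal. A further 309 genes were seen on the diabetic array only and at least 2-fold higher, led by Myom3 (at least 70.8-fold) and Wdr86 (at least 36.2-fold). On the control array only, 214 genes were seen with a bound of at least 2-fold, led by Tob2 (at least 170-fold lower in the diabetic) and Hsd3b5, a male-biased steroid dehydrogenase gene (at least 168-fold lower).

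Among metabolic lists, cholesterol synthesis genes were lower in the diabetic, with a median of -0.41 over 22 genes, below all 10000 random lists. Of these, 2 were at least 2-fold lower and 1 at least 2-fold higher, and Cyp51, the lanosterol demethylase gene, stood at -0.95 and Sqle, which makes squalene epoxide, at -0.88. All 12 measured fatty acid synthesis genes were lower, with a median of -0.29 at the 1.22 percentile, none by 2-fold. The lipogenic regulator Srebf1 differed by -0.92, Fads2 by -0.82, Acaca by -0.63 and Elovl5 by -0.62. The call for this list was lost without the filter on background. The list of fatty acid oxidation genes and PPAR-alpha targets had a median near 0 (0.05 over 19 genes, and from -0.01 to 0.26 across the alternatives), yet lay at the 99.3 percentile, since most random lists matched on expression lay lower. Apart from Cyp4a14 and Cyp4a10 no member was at least 2-fold higher, with Ehhadh (0.85) and Acot1 (0.81) next, and 1 was at least 2-fold lower. Lipid droplet genes had a median of 0.29, just past the upper mark of the central 95%, with Mogat1 (3.52), G0s2 (1.65), Pparg (0.95) and Plin5 (0.72) highest, but the call was lost in 7 of 10 alternatives. These include median centring and the 75th percentile over probes above background on all arrays. Both subtract a single constant per array, so the losses there came from new random draws or slight changes of the expression bins. Urea cycle and amino acid breakdown genes lay at the 98.6 percentile with a median of only 0.06, which ranged from -0.05 to 0.22 across the alternatives, 1 of which (no filter on background) ended the call, and Got1 (0.68), Nags (0.18), Ass1 (0.16) and Gls2 (0.09) were highest. Gluconeogenesis genes did not stand apart, with a median of -0.21 over 10 genes, and neither did those of insulin signalling (-0.17 over 11) or glycolysis (-0.22 over 12).

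Genes that differ by sex in mouse liver moved apart. The 5 measured male-biased genes were all lower, with a median of -0.89 at the 0.02 percentile, including Slco1a1, the fatty acid elongase gene Elovl3 (-3.11), Nudt7 (-0.89) and Cyp4a12a (-0.67). The 7 female-biased genes had a median of 1.04, above all random lists, and 4 were at least 2-fold higher: Cux2 (2.66), Acot3 (1.93), Cyp2b13 (1.76) and Cyp3a44 (1.04).

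Lists of blood, immune and stromal cells were lower on the diabetic array. Lymphocyte markers had a median of -0.74, with 5 of 13 at least 2-fold lower and Gzma (-2.46), Jchain (-2.20), Nkg7 (-2.11) and Cd2 (-1.48) lowest. MHC class II genes had a median of -0.92 over 7 genes, led by H2-Aa (-1.55), H2-DMb1 (-1.31), H2-Eb1 (-1.25) and H2-DMa (-0.92). The Kupffer cell list had a median of -0.52 (Folr2 -2.23, Adgre1 -0.82, Cd68 -0.71, Cd163 -0.64), that of matrix genes -0.60 (Pdgfrb -2.15, Col3a1 -1.83, Vim -1.08, Col1a2 -0.86) and that of endothelial markers -0.36 (Pecam1 -0.78, Stab2 -0.76, Cdh5 -0.69, Stab1 -0.69). Neutrophil markers had a median of -0.48, with 2 of 8 at least 2-fold lower and 1 at least 2-fold higher (S100a9 -1.59, Retnlg -1.56, Ngp -0.89, Mpo -0.51), cytokine genes one of -0.48, with 3 of 13 at least 2-fold lower and 1 higher (Cxcl1 -3.17, Ccl2 -1.81, Il1b -1.13, Ccl5 -0.90), and erythroid genes one of -1.21 (Slc4a1 -4.35, Car2 -1.43, Alas2 -1.21, Hbb-bt -0.43). Immediate early genes, which answer within minutes to stimuli and to tissue handling, were lower in all 12 cases with a median of -0.86, and Egr1 (-3.54), Atf3 (-2.15), Fosb (-1.55) and Fos (-1.48) were lowest. Cell cycle genes had a median of -0.27 at the 2.32 percentile, with 4 of 14 at least 2-fold lower, among them Mcm6 (-3.81), Mki67 (-2.53), Mcm5 (-2.11) and Ccna2 (-1.57). The call was lost in 1 alternative, which subtracts a single constant per array. That loss came from new random draws or slight changes of the expression bins and not from the scaling. Interferon response genes went the other way, with a median of 0.53 over 19 genes at the 99.97 percentile, led by Usp18 (2.74), Oasl1 (1.48), Ifit1 (1.15) and Zbp1 (0.81).

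These lists stood beside genes of the exocrine pancreas that differed between the arrays, from a source that was not settled. The list of pancreas, muscle and fat genes had a median of -0.60 with Cpa1 at -4.96, Try4 at -3.93, Ctrb1 at -3.56 and Cela1 at -0.89, and its call was lost when genes had to be above background on all 4 arrays. Of 27 acinar pancreas genes, chosen after the first values were seen, 22 were measured on the control and diabetic arrays and 21 of them were at least 2-fold higher on the control array, with a median of 4.15 (17.7-fold). They make up 21 of the 596 genes lower in the diabetic. On the metformin array 22 of the 27 genes, not all the same ones, were measured and were lower than on the control array by a median of 4.56-fold. On the combination array 11 were measured, with a median 37.4-fold lower before centring, and 12 more were seen on the control array only.

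**Figure D1:**
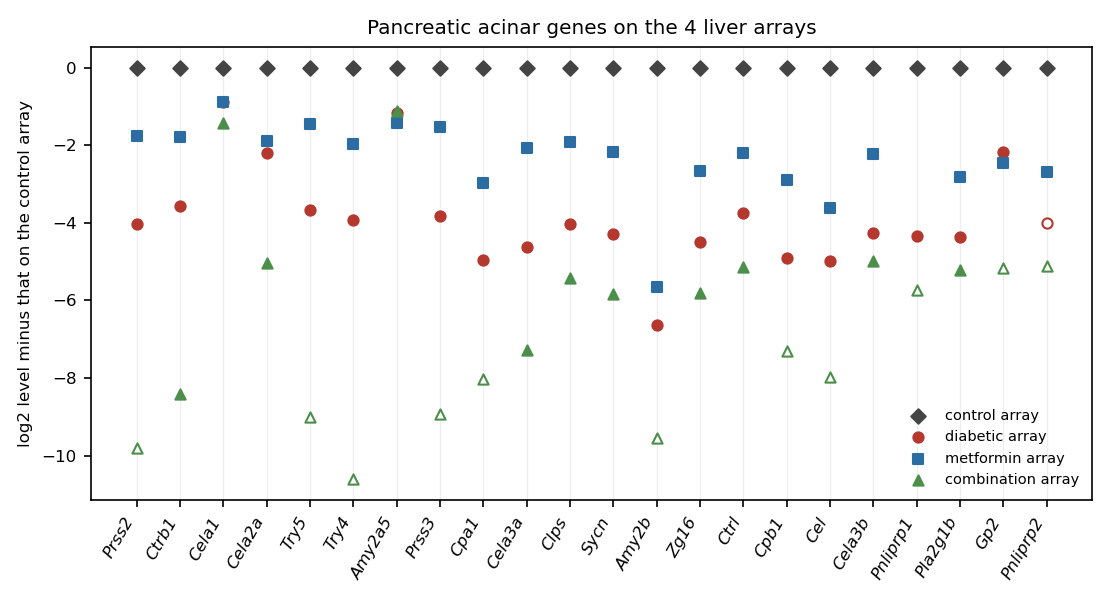
Pancreatic acinar genes on the 4 liver arrays. The x axis lists 22 of the genes above background on the control array, and the y axis gives each array's log2 level minus the control array's; filled symbols are above background and open symbols are not. The metformin points lie mostly above the diabetic points, and the combination points are the lowest for most genes.

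The second comparison asks how liver of diabetic mice given metformin differed from untreated diabetic liver. On the metformin array cell cycle, lymphocyte, matrix, interferon and immediate early genes were higher, cholesterol synthesis genes were higher, and genes of the unfolded protein response were lower. Of these, the cell cycle, lymphocyte, matrix, immediate early and cholesterol synthesis lists had stood apart below the control on the diabetic array. Against the control array, immediate early genes on the metformin array had a median of 0.19 and did not stand apart. Matrix (0.41), cholesterol synthesis (0.50), lymphocyte (1.16) and cell cycle genes (1.59) still stood apart above it. Of 12 heat shock genes, a group chosen after the first values were seen and without a percentile, 5 were at least 2-fold lower, and 3 with the authors' values. The imprinted transcript Meg3 was 44.6-fold higher, the centromere protein gene Cenpm 37.4-fold and the DNA replication gene Mcm6 32.7-fold. The endoplasmic reticulum degradation gene Derl3 was 20.8-fold lower, the leptin receptor gene Lepr 16.8-fold lower and the inducible HSP70 gene Hspa1a 8.11-fold lower. Of 13900 genes measured, 1344 were at least 2-fold higher and 429 at least 2-fold lower; centring each array on its median gave 1062 and 624.

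Also among the highest were the imprinted gene Dlk1 (27.4-fold), Cib3 (18.7-fold), the hydroxyacid oxidase gene Hao2 (17.6-fold), Mrap2 (16.3-fold) and the cytotoxic lymphocyte gene Nkg7 (16.3-fold). Also among the lowest were Camk2b (11.1-fold lower), Ibtk (9.45-fold), Icam4 (8.67-fold), Trim12a (7.94-fold) and the heat shock gene Hsph1 (7.24-fold). Seen on 1 array only with bounds of at least 2-fold were 502 higher genes, led by Tob2 (at least 158-fold) and the sulfotransferase gene Sult3a1 (at least 60.2-fold), and 116 lower ones, led by Ifi202b (at least 31.8-fold lower) and Defb26 (at least 24.5-fold lower). Tob2 rests on 1 probe that was near 3.5 in log2 over the 75th percentile on the other 3 arrays and below background on the diabetic array alone.

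Of 21 cholesterol synthesis genes, 19 were higher on the metformin array and 7 by at least 2-fold, with a median of 0.72 (1.64-fold), above all random lists. Sqle stood at 2.70, Cyp51 at 2.40 and Msmo1 at 1.42. Bile acid genes had a median of -0.36 over 14 genes at the 0.20 percentile, with Cyp8b1, which sets the share of cholic acid, at -1.91 and Cyp7a1 at -0.72, Baat at -0.66 and Cyp27a1 at -0.55. Fatty acid oxidation genes and PPAR-alpha targets had a median of -0.28 (Cpt2 -0.66, Ppara -0.56, Acot1 -0.36), lost in 2 of 10 alternatives and with 1 of 16 at least 2-fold higher, and urea cycle and amino acid breakdown genes one of -0.31 (Got1 -1.17, Gls2 -0.53, Sds -0.47, Tat -0.38), lost in 1. Unfolded protein response genes were lower in 13 of 14 cases with a median of -0.77, below all random lists, and the chaperone genes Sdf2l1 (-1.64), Creld2 (-1.38), Dnajb9 (-1.31) and Hyou1 (-1.02) were lowest, and 1 member was at least 2-fold higher. Male-biased genes had a median of 0.15 over 6 genes at the 99.3 percentile (Elovl3 1.02, Slco1a1 0.62, Cyp4a12a 0.34), between -0.06 and 0.55 across the alternatives and not apart with outlier spots kept. Of these 6 genes, 3 were lower. Against the control array all 9 measured male-biased genes stayed lower, with a median of -0.74 at the 0.01 percentile. Female-biased genes did not stand apart from the diabetic array (median 0.13 over 8 genes, 3 at least 2-fold higher and 1 lower). Against the control array their median was 1.02 over 6 genes, above all random lists. NRF2 and antioxidant genes lay at the 98.4 percentile although their median was -0.03, and from -0.17 to 0.15 across the alternatives, with Nqo1 (just under 2-fold), Hmox1 (0.78), Txnrd1 (0.41) and Gsta2 (0.41) highest. Gluconeogenesis genes did not stand apart, with a median of -0.13 over 10 genes, nor did fatty acid synthesis (-0.22 over 12), AMPK, mTOR and metformin transport (-0.24 over 14) or oxidative phosphorylation (-0.23 over 17).

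Cell cycle genes had the largest list median of this comparison, 2.65 (6.27-fold), with 9 of 11 at least 2-fold higher, including Mcm6 (5.03), Mcm5 (3.65), Ccnb1 (3.18) and the proliferation marker Mki67 (3.02). Lymphocyte markers had a median of 1.80 (3.49-fold), with 9 of 13 at least 2-fold higher and Nkg7 (4.02), Gzma (3.59), Cd3g (3.14) and Cd2 (3.01) in front. All 15 matrix genes were higher, 10 by at least 2-fold, with a median of 1.25, led by Pdgfrb (2.53), Col3a1 (2.25), Mmp2 (1.90) and Timp1 (1.86). Interferon response genes had a median of 1.30 with 11 of 19 at least 2-fold higher (Ifit2 2.34, Rsad2 1.84, Gbp2 1.77, Ifi44 1.76), and MHC class II genes one of 1.26 (H2-Eb1 1.39, H2-DMb1 1.38, H2-DMa 1.28, H2-Ab1 1.24). All 13 cytokine genes were higher with a median of 0.82, led by Ccl2 (3.92), Ccl5 (3.35), Cxcl9 (2.12) and Il1b (1.36). Immediate early genes had a median of 1.46 (Egr1 2.88, Fos 2.24, Klf6 2.16, Fosb 1.94). Smaller medians were found for endothelial markers (0.48, led by Lyve1 1.04, Eng 0.71, Cdh5 0.68 and Kdr 0.59), erythroid genes (0.51, led by Slc4a1 1.78, Car2 1.08, Alas2 0.51 and Hbb-bt 0.18) and senescence genes (0.30, with Cdkn2b 1.06, Gdf15 0.72 and Lmnb1 0.65). Among senescence genes 1 was at least 2-fold lower, and that call was lost in 2 of 10 alternatives. Kupffer cell markers were mixed, with a median of 0.57 and a mean of 0.35 (standard error over members 0.31): Folr2 (2.69), Cd68 (0.93), Adgre1 (0.92) and Timd4 (0.84) were highest, while 4 of 13 were lower and 2 of them by at least 2-fold, Cd163 (-1.85) and Marco (-1.39). Beside these lists, hepatocyte genes were lower by a median of -0.30 at the 0.20 percentile (Hpd -0.48, Apoa1 -0.35, Alb -0.33, Ahsg -0.32), a call lost with quantile normalization and the authors' values, and 16 of 21 measured acinar pancreas genes were at least 2-fold higher.

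**Figure D2:**
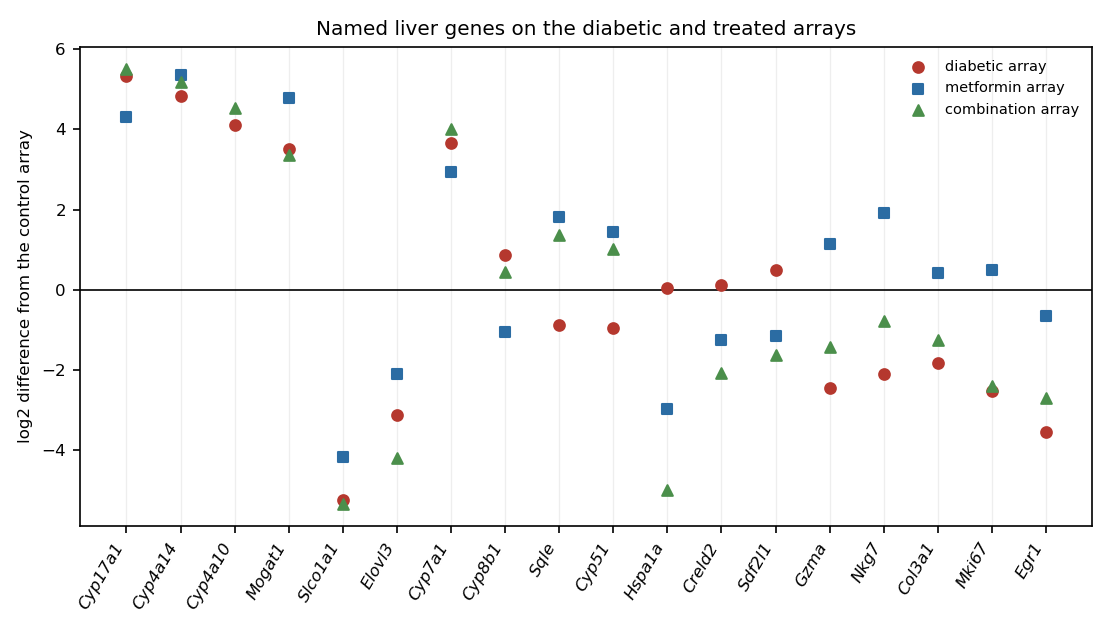
Log2 differences of 18 named genes from the control array (y axis) on the diabetic (circles), metformin (squares) and combination (triangles) arrays, 1 array each; combination values are after the median of all genes is taken off, and a symbol is missing where spots were left out as outliers. Sqle and Cyp51 lie below 0 on the diabetic array and above 0 on both treated arrays, while Cyp4a14, Mogat1 and Cyp7a1 stay above 2 and Slco1a1 below -4 on all 3.

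The third comparison asks how liver of mice given the combination differed from untreated diabetic liver. The median of all 14108 measured genes lay at -0.20, mostly because fewer bright spots were left out as outliers on the combination array, so values of this comparison are given after that shift is taken off. The centromere protein gene Cenpm was 37.7-fold higher on the combination array, Cyp2d22 28.8-fold and Meg3 18.1-fold. Derl3 was 61.3-fold lower and the HSP70 genes Hspa1a and Hspa1b were 32.6-fold and 14.6-fold lower. Cholesterol synthesis genes were higher and unfolded protein response genes lower than on the diabetic array. The metformin comparison uses the same single diabetic array, so like directions in both are not independent. Cholesterol synthesis genes were low on that array against control (-0.41), yet stood above the control on the metformin (0.50) and combination arrays (0.32 after centring). Before centring, 318 genes were at least 2-fold higher and 1327 lower, which puts 80.7% of these genes on the lower side. After centring there were 495 and 890 (64.3% lower), with the authors' values 517 and 843 (62.0%), with quantile normalization 501 and 787 (61.1%), and with the 75th percentile over probes above background on all arrays 580 and 800 (58.0%).

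Also among the highest genes were the sulfotransferase genes Sult2a3 (17.5-fold) and Sult2a5 (15.2-fold), Mgst2 (11.9-fold) and the ganglioside synthase gene B4galnt1 (11.8-fold). Also among the lowest were the chymotrypsinogen gene Ctrb1 (25.1-fold lower), Wdr86 (22.4-fold), Dmbt1 (17.7-fold), Rtp3 (15.6-fold) and Spsb4 (14.4-fold). Seen on 1 array only with bounds of at least 2-fold, counted before centring and with the folds given after it, were 112 higher genes, led by Tob2 (at least 184-fold) and Smad9 (at least 23.5-fold), and 265 lower ones, led by the trypsin genes Try5 (at least 23.3-fold lower) and Prss2 (at least 23.2-fold lower). Acinar pancreas genes were lower by at least 2-fold in 8 of 12 measured cases before centring.

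Of 22 cholesterol synthesis genes, 20 were higher and 6 by at least 2-fold, with a median of 0.72 (1.65-fold), above all random lists, and Sqle (2.27) and Cyp51 (1.99) were highest. Drug-metabolising cytochromes and their regulators had a median of 0.25 at the 99.7 percentile, with Cyp1a1, an aryl hydrocarbon receptor target, at 3.08, its relative Cyp1a2 at 0.89, the nuclear receptor gene Nr1i3 at 0.98 and Cyp2c55 at 0.39. Unfolded protein response genes had a median of -0.65 over 15 genes, below all random lists, with 4 at least 2-fold lower: Creld2 (-2.18), Sdf2l1 (-2.09), Ddit3 (-1.47) and Pdia4 (-1.03), and 1 at least 2-fold higher. Female-biased genes were higher, with a median of 0.67 and 3 of 9 at least 2-fold higher, among them A1bg (1.07) and Cyp3a44 (1.03), and Cyp2b13 at 0.76, a call lost when genes had to be above background on all 4 arrays. Male-biased genes had a median of -0.48 over 6 genes at the 0.09 percentile, with Cyp4a12a (-1.30), Elovl3 (-1.08), Slco1a1 (-0.53) and Nudt7 (-0.44) lowest. Acute phase genes had a median of only -0.10 over 17 genes, at the 0.23 percentile, with Saa3 (-1.63), Apcs (-0.97), Saa2 (-0.84) and Saa1 (-0.58) lowest, and 1 was at least 2-fold lower and 1 at least 2-fold higher. Gluconeogenesis genes had a median of 0.03 and did not stand apart, nor did fatty acid synthesis (-0.07) or lipid droplet genes (-0.05).

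Cell type and immune lists went in different directions in this comparison. Matrix genes had a median of 0.51 (Pdgfrb 1.62, Lum 1.24, Ccn2 0.92, Mmp2 0.73), immediate early genes 0.59 (Myc 1.43, Fos 1.23, Ier3 1.16, Dusp1 0.95) and lymphocyte markers 0.43 (Nkg7 1.33, Jchain 1.33, Gzma 1.04, and Cd2 just under 2-fold), while cytokine genes were mixed. Their median was 0.41 at the 99.7 percentile with Il1b (1.28), Vcam1 (0.88), Ccl2 (0.63) and Ccl5 (0.61) highest, but only 1 of 13 was at least 2-fold higher and 2 were at least 2-fold lower, Ccl3 (-2.66) and Ccl4 (-2.19), and the mean before centring was -0.31. Endothelial markers had a median of 0.34 (Cdh5 1.09, Pecam1 0.82, Kdr 0.70, Eng 0.50), erythroid genes 0.35 (Slc4a1 1.74, Car2 0.80, Hbb-bt 0.35, Alas2 0.31) and MHC class II genes 0.49 (H2-Aa 0.90, H2-Eb1 0.84, H2-Ab1 0.72, Cd74 0.49); the erythroid call was lost in 1 alternative and the MHC class II call in 2. Neutrophil markers were lower, with a median of -0.64 over 5 genes (Camp -2.42, Mpo -0.68, S100a9 -0.64, Retnlg -0.26). Kupffer cell markers had a median of -0.24 at the 2.49 percentile (Marco -2.37, Cd163 -1.78, Adgre1 -0.60, Clec4f -0.57), with 2 of 13 at least 2-fold lower and 1 higher, a call lost in 3 of 10 alternatives. Of these, 1 subtracts a single constant per array, so its loss came from new random draws or slight changes of the expression bins.

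The fourth comparison asks what differed when astragalus polysaccharide was added to metformin. The median of all 14363 genes lay at -0.19, and values are again given after that shift is taken off. Cell cycle, lymphocyte, interferon, cytokine and matrix genes were lower on the combination array than on the metformin array. Mcm6 was 18.4-fold lower, the cell cycle phosphatase gene Cdkn3 17.8-fold, and Fgf21, a fasting hormone of the liver, stood at -3.90. The kinase gene Camk2b was 11.8-fold higher, the glycogen-targeting phosphatase subunit gene Ppp1r3g 9.58-fold and Lepr 7.42-fold. Before centring, 158 genes were at least 2-fold higher and 1971 lower (92.6% lower). After centring there were 259 and 1470 (85.0% lower), with the authors' values 377 and 1315 (77.7%), with quantile normalization 383 and 1274 (76.9%) and with outlier spots kept 350 and 1441 (80.5%).

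Also among the highest genes were Mzt1 (10.3-fold), the Langerhans cell lectin gene Cd207 (9.44-fold), Smad9 (6.32-fold), Tlr12 (5.04-fold) and Psmc3ip (5.02-fold). Ctrb1 was 86.6-fold lower and Cela3a 32.6-fold lower, both pancreatic, and Fmr1nb (19.9-fold lower), the adipose-derived complement factor gene Cfd (14.1-fold) and Mrap2 (13.2-fold) completed the lowest. Seen on 1 array only with bounds of at least 2-fold, again counted before centring with folds after it, were 62 higher genes, led by Ifi202b (at least 22.5-fold) and Olfr1414 (at least 10.9-fold), and 634 lower ones, led by Prss2 (at least 111-fold lower) and Try5 (at least 108-fold lower). Acinar pancreas genes were at least 2-fold lower in 9 of 11 measured cases before centring.

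Cell cycle genes had a median of -2.28 (4.85-fold lower), with 9 of 10 at least 2-fold lower, among them Birc5 (-3.14), Mki67 (-2.88) and Mcm5 (-2.42). Lymphocyte markers were at least 2-fold lower in 12 of 14 cases with a median of -1.67 (Nkg7 -2.70, Gzma -2.56, Cd3g -2.32, Cd3d -2.04). Interferon response genes had a median of -1.40 with 10 of 16 at least 2-fold lower (Oasl2 -2.75, Ifi44 -2.57, Oasl1 -2.49, Zbp1 -2.35), cytokine genes one of -1.01 (Ccl2 -3.30, Ccl3 -3.19, Ccl4 -2.80, Ccl5 -2.75) and matrix genes one of -0.87 (Col1a1 -2.90, Timp1 -1.90, Col3a1 -1.67, Loxl2 -1.38). Kupffer cell markers (-0.79, with Folr2 -1.69, Adgre1 -1.53, Cd68 -1.09 and C1qc -1.01), MHC class II genes (-0.86, with Ciita -1.62, H2-DMb1 -1.19, H2-DMa -1.15 and H2-Eb1 -0.56), immediate early genes (-1.02, with Egr1 -2.03, Klf6 -1.65, Atf3 -1.57 and Fosb -1.35) and neutrophil markers (-0.65, with Camp 2.84-fold lower, S100a9 -1.45, Mpo -0.70 and Retnlg -0.61) were lower as well. The MHC class II call was lost in 1 alternative and the neutrophil call in 2. Endothelial markers (-0.01) and hepatocyte genes (0.29) did not stand apart.

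Metabolic lists mostly lay on the higher side. Urea cycle and amino acid breakdown genes had a median of 0.48 and all 10 were higher, led by Got1 (1.29), Sds (0.83), Arg1 (0.77) and Hal (0.63). Bile acid genes had a median of 0.39 at the 99.9 percentile, with Cyp8b1 (2.84-fold), Cyp7a1 (1.08), Cyp27a1 (0.86) and Abcc3 (0.52) highest, and drug-metabolising cytochromes one of 0.42 (Nr1i3 0.95, Cyp2c29 0.63, Cyp1a2 0.54, Cyp2b10 0.50), with 1 of 10 at least 2-fold lower. Oxidative phosphorylation genes were higher in 18 of 18 cases with a median of 0.32 at the 98.6 percentile (Atp5b 0.63, Ndufv1 0.48, Sdhb 0.42), lost in 2 of 10 alternatives. Before centring 17 of 18 were higher and their median was only 0.13. Centring also put all 11 measured hepatocyte genes above 0, although that list did not stand apart. Circadian clock genes had a median of 0.37 (Ciart 1.53, Per3 1.17, Tef 0.95, Dbp 0.71), with 2 of 15 at least 2-fold higher and 1 lower, lost without the filter on background, where the median before centring was -0.04. Male-biased genes had a median of -0.15 over 9 genes at the 0.13 percentile, with Elovl3 (-2.10), Cyp4a12b (-2.01), Cyp4a12a (-1.65) and Slco1a1 (-1.16) lowest, and its uncentred median of -0.35 ran from -1.35 to -0.07 across the alternatives. Lipid droplet genes had a median of -0.12 over 13 genes, with G0s2 (-3.14), Cidea (-2.11), Cidec (-1.93) and Mogat1 (-1.31) at least 2-fold lower, but 6 of 10 alternatives ended the call and their uncentred medians ran from -0.37 to 0.07. Cholesterol synthesis genes had a median of -0.10 over 23 genes at the 1.74 percentile (Mvd -1.07, Nsdhl -0.55, Dhcr7 -0.53, Sqle -0.44), and the call was lost in 2 alternatives, with uncentred medians from -0.32 to 0.003.

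**Figure D3:**
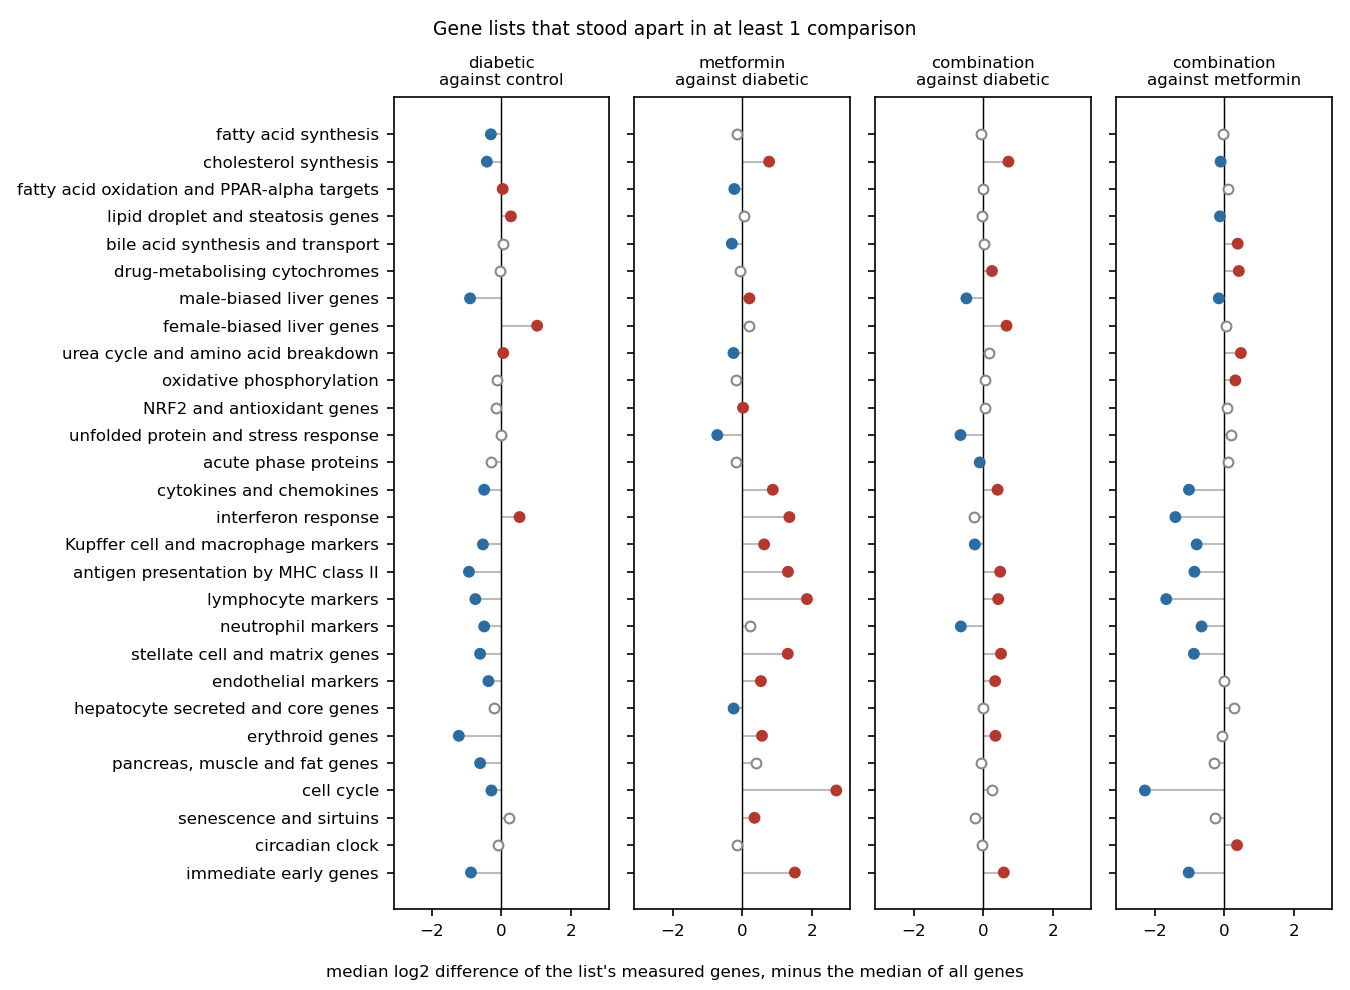
Median log2 difference of each gene list minus the median of all genes (x axis) for the 28 lists that stood apart in at least 1 of the 4 comparisons, 1 panel per comparison. Filled points lie outside the central 95% of random lists matched on expression, red on the higher and blue on the lower side; open points lie inside. Cell cycle and lymphocyte lists lie furthest right for metformin against diabetic and furthest left for combination against metformin.

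**Figure D4:**
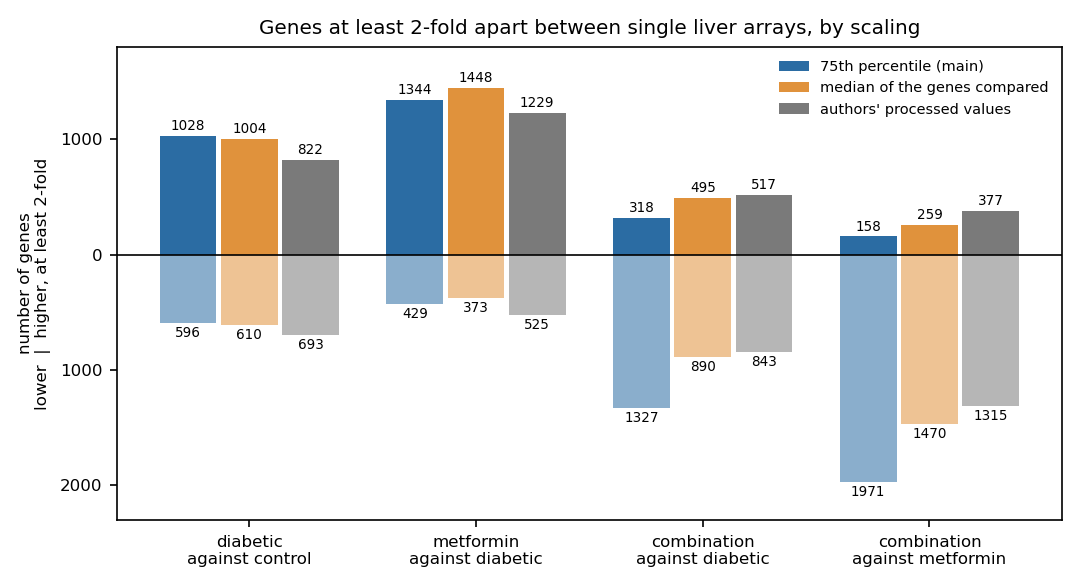
Number of genes at least 2-fold higher (full colour, upward) and lower (pale, downward) in each comparison of single arrays under 3 scalings. The combination comparisons hold more lower than higher genes under each scaling, with the largest imbalance under the main one.

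The last comparison asks how far genes that differed in the diabetic lay back toward the control on the treated arrays. Of 1511 genes measured on all 4 arrays and at least 2-fold apart between diabetic and control, 73.4% lay nearer the control on the metformin array and 78.0% on the combination array. Simulated unchanged arrays, which share the diabetic array, gave 81.1% (78.5 to 83.2% over 100 simulations), so over all these genes neither share exceeded the simulated one. That share is the one for arrays without a lasting difference between the groups. Where diabetic differences were real and a treatment changed nothing, another share would hold, which was not simulated. The simulation therefore cannot exclude a return toward the control. By direction, 86.1% of the 979 genes higher in the diabetic lay nearer the control on the combination array, above the simulated 77.9 to 84.5%, and 67.8% on the metformin array, below it. Of the 532 lower genes it was 63.2% on the combination array, below the simulated 77.8 to 84.9%, and 83.6% on the metformin array, within it. With the arrays centred on the median gene, the combination shares were 78.1% and 75.9%. The combination value lay further toward the control than the metformin value for 62.1% of the genes, where 50% would hold for exchangeable arrays. That share was 81.9% among the genes higher in the diabetic and 25.8% among the lower ones. With all arrays centred on the median gene it was 53.1%, made of 66.0% and 40.1%, and with the authors' values 55.5%. Differences of Cyp4a14, Mogat1 and Slco1a1 from control remained above 8-fold on both treated arrays.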

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

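Control probes for synthetic ERCC transcripts entered no comparison, and whether such RNA was added is not given in the sources used here. Some were above background on most spots of a treated or diabetic array and not of the control array. The probe ERCC-00009_60 had a median signal of 507 on the metformin array, where 100% of its 28 spots were above background, against 29.1 on the control array. The probe ERCC-00022_66 had a median signal of 133 on the diabetic, 128 on the metformin and 147 on the combination array, against 85.5 on the control array. The probe ERCC-00043_129 had a median signal of 131 on the combination array, where 65.7% of 35 spots were above background, against 114 on the control array. No explanation was tested for these probes.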

How the results depend on the processing

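Keeping outlier spots and centring on the median of the genes compared were chosen after seeing the data; the other alternatives were fixed before. With 1 array per group no replicate could be left out, and a slide block was not possible. No paired analysis was possible because each group has 1 array and no test was made. Of 121 recomputed counts and shares, 78 stayed within 1.5 times the main count or within the share's 95% binomial interval, and 43 moved. No share crossed 50% and no named gene with a difference of at least 2-fold changed sign in 2657 recomputed values, of which 1977 moved by at most 0.2 in log2. Gene lists stayed outside the central 95% on the same side in 1003 of 1060 values, and none crossed to the other side of the middle. This count includes the alternatives that subtract a single constant per array, under which a list's percentile could hardly change. For centring on the median of the genes compared, the main percentile was carried over. The count therefore overstates how well the calls held. Dim probes limit the rest: genes not well above background have only bounds.

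Without a filter on background, which adds dim genes, the higher and lower counts were 2133 and 1167 for diabetic against control, 2860 and 779 for metformin against diabetic, 672 and 2142 for combination against diabetic, and 366 and 3845 for combination against metformin; 61.5% of the diabetic genes then lay nearer the control with metformin and 71.9% with the combination. A 1.5-fold threshold, which admits smaller differences by construction, gave 2242 and 1472, 2421 and 1386, 914 and 3096, and 567 and 3765 in the same order, with shares of 68.3% and 74.2%.

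The scaling moved the combination comparisons. Higher and lower genes of combination against diabetic were 580 and 800 with the 75th percentile over probes above background on all arrays, 501 and 787 with quantile normalization, 517 and 843 with the authors' values, and 586 and 871 with outlier spots kept. The higher count was 495 when centred on the median of the genes compared and 205 with normexp, where the cause was not tested. For combination against metformin the higher count was 243 with the percentile over probes above background on all arrays, 383 with quantile normalization (1274 lower), 270 with median centring, 377 with the authors' values, 350 with outlier spots kept and 259 when centred on the genes compared. The share of diabetic genes further toward the control with the combination than with metformin fell to 57.7% with the percentile over probes above background, 55.0% with quantile normalization, 58.1% with median centring, 55.5% with the authors' values, 55.1% with outlier spots kept and 53.1% when centred on the genes compared. Apart from normexp, these scalings bring the median difference of the combination array nearer 0 in at least 1 of its comparisons, which moves genes from the lower to the higher count by construction.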

Other observations

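The tests of a lower share of hepatocytes and of a brighter array, below, were chosen after their results were seen; the other tests were fixed before. Set against the control array directly, both treated arrays were lower in genes of glucose use and fat synthesis. These comparisons were not among the 4 fixed ones, and the genes named were chosen after their values were seen. On the combination array, values after the median of all genes is taken off, fatty acid synthesis genes had a median of -0.75 over 13 genes, below all 10000 random lists, with Elovl6 at -1.73, Acaca at -1.41 and Fasn at -1.24. Glycolysis genes had a median of -0.53 at the 0.05 percentile, with the liver pyruvate kinase gene Pklr at -2.64. On the metformin array the medians were -0.66 over 12 fatty acid synthesis genes at the 0.01 percentile and -0.58 over 12 glycolysis genes at the 0.04 percentile, with Pklr at -1.15. These 4 calls held under all 10 alternatives, although those that subtract a single constant per array could hardly have ended them. The diabetic array, set against the same single control array, was low in these lists too. There 11 of 12 glycolysis genes were lower, 4 by at least 2-fold, with Pklr at -1.17, although that list did not stand apart. All 12 fatty acid synthesis genes were lower, at the 1.22 percentile. Against the diabetic array neither list stood apart on either treated array, so these differences from control cannot be credited to the treatments.

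Interferon response genes on the metformin array lay above the control too, with a median of 1.72 and 15 of 18 at least 2-fold higher, while on the combination array their median was 0.10 after centring and they did not stand apart. Circadian clock genes on the metformin array had a median of -0.64 against control at the 0.01 percentile, with Nfil3 (-1.31) and Per3 (-1.14) lowest. Neutrophil markers on the combination array had a median of -1.83 against control over 7 genes, 5 of them at least 2-fold lower. The imprinted transcript H19 was higher than on the control array by 4.80 on the diabetic, 6.39 on the metformin and 5.49 on the combination array, the last after centring. Of 12 heat shock genes, chosen after the first values were seen, 7 were at least 2-fold lower on the metformin than on the control array and 9 on the combination array before centring, against 0 on the diabetic array. With the authors' values these were 6, 6 and 0. The labels give male mice, and the Y-linked genes Eif2s3y and Uty were above background on all 4 arrays. The X-inactivation transcript Xist was above background on the metformin and combination arrays, at low levels of -3.98 and -3.22 in log2 against the 75th percentile. Of 3 Kdm5d probes, 1 was above background on the control and combination arrays each and 0 on the others. Ddx3y had a value on the control array only, because its 1 probe was left out as an outlier on the other arrays. Its missing values there do not show that the transcript was absent. No explanation was tested for the other values given here.

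Pancreatic acinar genes differed between the arrays, with a median of 4.15 in log2 between control and diabetic. Normalization between arrays is argued against: with the authors' values the median over 22 genes was 4.10. Carry-over of pancreatic tissue or RNA in different amounts may account for it and cannot be told apart from expression in these livers. Its test used islet hormone genes, which whole pancreas would bring along: Ins1 and Ins2, the only 2 of 7 measured, had a median difference of -0.047 between control and combination before centring, against 5.23 for the acinar genes, but they differed from each other with an SD of 0.60 and Gcg, Sst and Pyy were below background on all 4 arrays. The SD of the acinar genes was 2.15, and Cela1, at 0.89 between control and diabetic, moved least. A difference tied to the diabetic state stays open and untested.

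Immune, matrix and cell cycle genes were higher on the metformin array than on the diabetic array. Against the control array, cell cycle (median 1.59), lymphocyte (1.16), cytokine (0.63) and matrix genes (0.41) stood apart on the higher side too. MHC class II (0.16), Kupffer cell (0.02), endothelial (-0.18) and erythroid genes (-0.41) did not stand apart from the control, so their difference from the diabetic array goes with low values on that array. A lower share of hepatocytes, with the other cell types in unchanged proportions, would lift markers of all of them alike. The mean of the lymphocyte list exceeded that of the endothelial list by 1.46 with a standard error over members of 0.39, which speaks only to that even form. This error is a spread between genes on single arrays and not between mice. Hepatocyte genes were lower on the metformin array by a median of -0.30, a call lost in 2 alternatives. For a brighter array the authors' values were used, in which all arrays have the same median and 75th percentile. There the lymphocyte, matrix and cell cycle lists had means of 1.79, 1.29 and 2.38, with standard errors over members of 0.38, 0.20 and 0.44, against 1.87, 1.27 and 2.40 in the main values. The main values were already scaled to the 75th percentile, and the authors' values of the metformin array correlated with its log2 signal at 0.999. The settings could therefore hardly differ, and the check cannot decide on a brighter array. It shows only that the differences did not depend on the choice between these scalings. A brighter array and a lower share of hepatocytes with uneven changes of the other cell types stay open. More lymphocytes in the piece of liver taken, an effect of metformin and a difference between mice stay open as well, and with 1 array per group none of them was tested.

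More genes were lower than higher on the combination array than on the diabetic array. Normalization is a likely part of this and cannot be told apart from a real excess of lower genes. With the authors' values 62.0% of the genes at least 2-fold apart were lower, against 80.7% in the main values, which lies between the 40 to 60% set beforehand for normalization as the whole cause and the 70% set against it. With outlier spots kept, an alternative added later, it was 59.8%. An effect of the treatment stays open.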
